A study of Mus musculus with 2 samples.

How the data were processed

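Nuclei from frozen right-half cortex of female 5xFAD mice aged 5 months were profiled by droplet single-nucleus RNA-seq, with 1 library of control mice and 1 library of Cre mice, each a pool of 3 mice. The deposited matrices hold raw UMI counts for all barcodes, 32285 genes by 1753535 barcodes in the control library and by 1565884 in the Cre library. Per the submitters' processing notes the authors aligned the reads to mm10 with Cell Ranger 7.0.1, whereas the file headers name Cell Ranger 4. Whether intronic reads were counted is not given in the sources used here.

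Barcodes with at least 500 UMIs numbered 10387 in the control and 10203 in the Cre library. Nuclei were called from these with at least 300 genes, under 5% mitochondrial UMIs and a Dirichlet-multinomial test against the profile of barcodes with up to 100 UMIs (10000 simulations, Benjamini-Hochberg rate 0.001). The ambient test removed 26 control and 13 Cre barcodes and the other limits 25 and 10. Scrublet, through scanpy, removed 875 and 894 doublets and left 9461 and 9286 nuclei. Counts were scaled to 10000 per nucleus and log transformed, and 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1 (seed 0) were used on both libraries together without integration. Clusters were named from fixed marker sets. The software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, numba 0.67.0 and matplotlib 3.10.9.

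UMIs were summed over the nuclei of a class in each library and given as CPM without mitochondrially encoded genes. Ratios carry exact conditional binomial intervals, CPM exact Poisson intervals and shares Clopper-Pearson intervals, all at 95%. List medians carry 95% percentile intervals from 2000 Poisson draws around the observed counts, and percentage point differences carry approximate Newcombe intervals. A list median is the median log2 ratio over members with at least 10 UMIs over both libraries, with a prior worth 0.5 UMI in the smaller class total, and its percentile comes from 10000 random lists matched on expression. For a group at 0 UMIs the lower limit of the ratio interval is given. Beside it stands the fold against a floor of 3 counts in that class, called its bound, which leaves out counting error. With 1 library per group no test between groups was run and no changed genes were counted.

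The gene lists, the main settings and the rule for named genes were fixed before the data were examined. Named genes came from classes with at least 50 nuclei in each library, ranked by the bound of the ratio interval nearest 1, with at least 50 UMIs over both libraries, a CPM at least 2 times that of the ambient profile and no nucleus holding more than 10% of the UMIs. Up to 10 genes each way were taken in microglia-like, 5 in astrocyte-like and oligodendrocyte-like and 3 in other nuclei, where the interval excluded 1, together with fixed genes and up to 4 examples per list. Genome positions came from GENCODE vM21. Clec7a and Mx1 are not analysed here, and some other genes that the rule takes are not reported here. Also left out, after their values were seen, were Ptgds in astrocyte-like and oligodendrocyte-like nuclei, Apod in oligodendrocyte-like nuclei and Egr3 in inhibitory neuron-like nuclei, since the estimated empty droplet RNA accounted for their level or their difference. All of these were lower in the Cre library: Ptgds (ratio 0.428 in astrocyte-like and 0.807 in oligodendrocyte-like nuclei), Apod (0.858) and Egr3 (0.0890). Other list examples below their empty droplet level were kept. Among those were B2m and H2-K1, higher in Cre oligodendrocyte-like nuclei, and Pfkp and Hk1, lower in Cre microglia-like nuclei. The omission thus ran in 1 direction. Aldoa and Ddit3 have duplicate symbols, and the identifier with more UMIs was used.

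Several choices were made after values had been seen. The expected doublet rate was not fixed in advance: it was run at 0.06, at 0.05 and then at 0.08, and 0.08 was adopted after the clusters and the microglia counts per library had been seen. The removed shares of control and Cre barcodes were 6.84% and 8.43% at 0.06, 2.76% and 8.10% at 0.05, and 8.47% and 8.78% at 0.08. The limits for naming clusters were also set after the clusters and counts had been seen, and they left 17.8% of control and 10.8% of Cre nuclei unnamed. The ambient profile of barcodes with up to 100 UMIs was rich in transcripts of lung and epithelium and missed the main group of empty droplets, at 100 to 200 UMIs. It was kept as designed, and the profile of those droplets was added as an alternative, by which 39 of 113 named gene entries, 12 of them in microglia-like nuclei, were below 2 times their empty droplet level in the library where they were higher. The planned ambient subtraction took 36.1% and 41.9% of UMIs from astrocyte-like, 50.0% and 46.4% from oligodendrocyte-like and 44.5% and 50.0% from microglia-like nuclei of the control and Cre libraries, with a cap of 50%, so its values in glia are unreliable. For the barcode overlap, the first reading of the control genes had 0.018 shared barcodes expected and could decide nothing, and the reading with most expected (39.9) was used. Some tests of explanations were first run in a form that departed from their written wording in 4 places. They were returned to that wording, and where it left room all readings were run and the lowest value decided, after the first values had been seen.

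Alternatives covered the UMI minimum, a rank-based UMI threshold, doublet removal and its rate, clustering of each library alone, the clustering resolution, TMM scaling, weighting of nuclei, ambient subtraction, the UMI minimum for list members, thinning depth, the choice of microglia-like nuclei and pooling within clusters.

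The calculations were tested on simulated data made from these libraries. Class sums were drawn as Poisson counts around the pooled means, as the intervals assume, so their coverage checks the calculation only. It does not cover variation between nuclei, mixed nuclei or empty droplet RNA. In the data the SD of log2 ratios over genes of microglia-like nuclei was 0.732, against 0.358 from counting alone. Intervals held the true ratio of unchanged genes in 96.3% of cases in microglia-like, 96.1% in astrocyte-like, 96.3% in oligodendrocyte-like and 95.4% in excitatory neuron-like nuclei. In microglia-like nuclei the direction of a change of 1.5, 2 and 4 times was found for 50.0%, 82.9% and 98.4% of changed genes.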

Results

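The data consisted of 2 single-nucleus RNA-seq libraries from frozen cortex of female 5xFAD mice, which carry human transgenes that cause amyloid plaques, at 5 months of age. The control library came from mice homozygous for a floxed Inpp5d allele without Cre. The Cre library came from littermates that carried the same floxed allele and a tamoxifen-dependent Cre recombinase driven by Cx3cr1, a gene of microglia and other myeloid cells. All mice had received tamoxifen diet for 2 weeks from weaning at about 3 weeks. Each library was 1 pool of nuclei from 3 mice, so each group had 1 library and no difference reported here has a replicate check. The control library held 54218706 UMIs (unique molecular identifiers, 1 per captured RNA molecule) over 1753535 barcodes, and the Cre library 50802754 UMIs over 1565884 barcodes. After calling and doublet removal, 9461 control and 9286 Cre nuclei remained, against a capture target of about 3000 per library. All intervals are 95% intervals for counting error within these 2 pools and do not cover variation between mice. Those of UMI sums also leave out variation between nuclei.

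The first comparison asked how much of the targeted transcript remained. Inpp5d (ENSMUSG00000026288) encodes SHIP1, a phosphatase that acts on signalling phosphoinositides in immune cells, and lies on the plus strand of chromosome 1 from 87620312 to 87720507 in mm10, with up to 28 annotated exons in 1 transcript. In microglia-like nuclei it was lower in the Cre library, at 369 CPM (counts scaled to a common class total, 330 to 412, from 321 UMIs) against 1108 CPM in the control library (985 to 1243, from 291 UMIs). The ratio was 0.333 (0.284 to 0.392), a log2 ratio of -1.58. After thinning every nucleus to 500 UMIs, 17.1% of 971 Cre nuclei (14.8 to 19.6) and 49.2% of 185 control nuclei (41.8 to 56.6) held an Inpp5d UMI, with 3 Cre and 0 control nuclei too shallow to be thinned. Without thinning the shares were 23.8% and 73.5%, at median depths of 772 and 858 UMIs. Excitatory neuron-like nuclei, taken as background, held an Inpp5d UMI in 0.0716% of Cre and 0.0684% of control nuclei after thinning and in 1.00% and 0.729% before it, at median depths of 4427 and 4498 UMIs. The labels do not say which exons are floxed, and tags from outside them are still counted, so the remaining count does not measure how many cells kept the allele. The log2 ratio stayed negative under the 19 alternatives that gave a value. It shrank to -0.63 with a minimum of 1000 UMIs per nucleus and to -0.57 when each library was clustered alone. At a doublet rate of 0.06 it was -0.96, and -0.83 with the mixed microglia and oligodendrocyte cluster added. Other choices moved it further from 0, to -2.06 with each nucleus weighted alike and -2.01 with microglia chosen by markers. In nuclei with few neuron marker UMIs it lay between -2.18 and -2.11.

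The second comparison asked whether the cell classes were present in the same shares. Microglia-like nuclei, all in 1 cluster led by Lrmda, Ly86, Runx1 and Apbb1ip, made up 10.5% of the Cre library (974 nuclei, 9.87 to 11.1) and 1.955% of the control library (185 nuclei, 1.69 to 2.25), a ratio of 5.36 (4.58 to 6.31). Clustering again without 455 genes that differed between the libraries gave 972 and 182 such nuclei. Oligodendrocyte precursor-like nuclei were also higher, at 3.47% against 2.45% (ratio 1.41, 1.19 to 1.68), whereas fibroblast-like nuclei were lower, at 0.538% against 1.27% (0.425, 0.299 to 0.595), as were striatal projection neuron-like nuclei, at 2.02% against 2.75% (0.737, 0.607 to 0.892). The other named classes had ratios from 0.883 (pericyte or smooth muscle-like) to 1.16 (endothelial-like), each with an interval that included 1. Among these were excitatory neuron-like (45.1% against 46.4%), inhibitory neuron-like (8.84% against 8.69%), astrocyte-like (8.36% against 8.79%) and oligodendrocyte-like nuclei (8.42% against 8.09%). The neuron shares cover named clusters only and so depend on the naming rule. Clusters left unnamed held 10.8% of Cre and 17.8% of control nuclei. Of these clusters, 1 with leading genes Pbx3, Lgr5, Ptpro, Meis2 and Gad1 held 22 Cre and 552 control nuclei. That cluster matched 6 of 15 inhibitory and 5 of 15 excitatory neuron markers. Unnamed clusters that matched excitatory neurons best held 252 Cre and 538 control, 223 and 51, 147 and 141, and 17 and 31 nuclei. An unnamed cluster with microglia and oligodendrocyte markers held 144 Cre and 104 control nuclei. The microglia-like log2 share ratio of 2.42 was above 0 under the 17 alternatives that gave a value, but it was 1.07 with a minimum of 1000 UMIs per nucleus and 1.72 when the libraries were clustered apart. Over all barcodes of each library, with no calling or clustering, the median CPM ratio of the 20 microglia markers was 2.31 (2.22 to 2.43), less than the ratio of nuclei. On the same measure oligodendrocyte precursor markers were not detectably different (1.04, 0.982 to 1.09). Markers of excitatory neurons (0.941, 0.914 to 0.961), inhibitory neurons (0.791, 0.753 to 0.824), astrocytes (0.841, 0.821 to 0.871) and oligodendrocytes (0.788, 0.764 to 0.824) were lower.

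**Figure D1:**
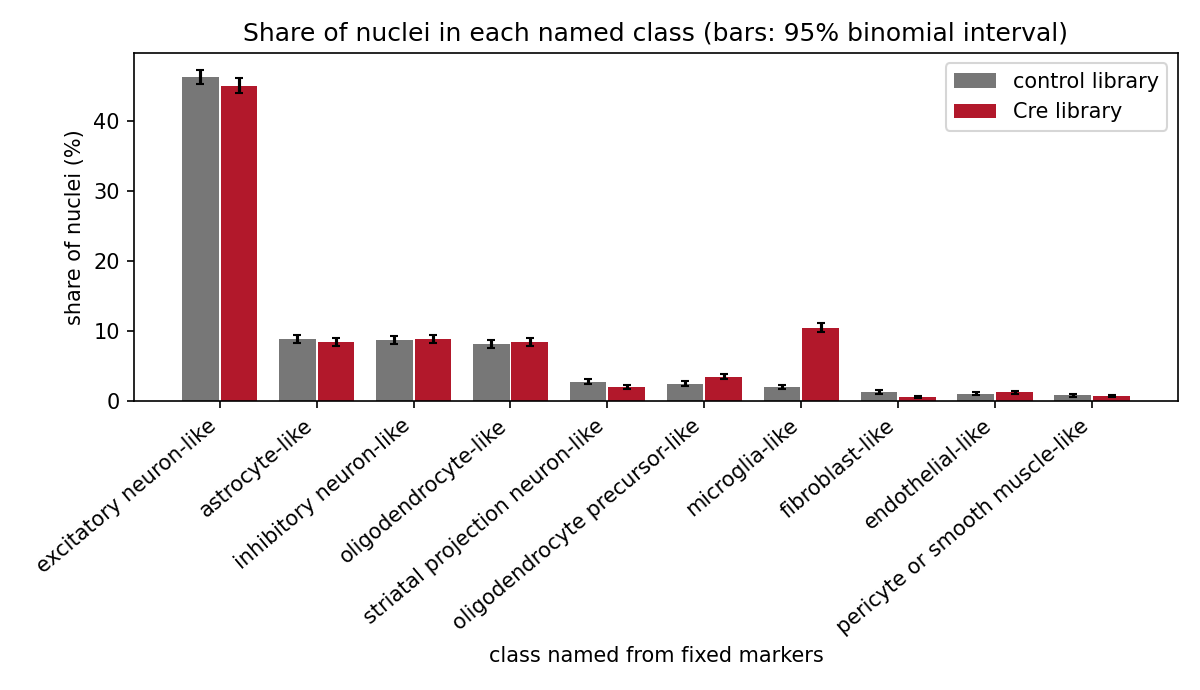
The vertical axis is the share of all nuclei of a library in percent, the horizontal axis the named class, with grey bars for the control library, red bars for the Cre library and error bars for the 95% binomial interval. Microglia-like nuclei stand at 1.955% in the control and 10.5% in the Cre library, whereas excitatory neuron-like nuclei stand at 46.4% and 45.1%.

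The third comparison asked how the state of the microglia-like nuclei differed. Transcripts linked to microglia around plaques were higher in the Cre library, and so were the summed markers of monocytes or neutrophils in the same nuclei (ratio 2.14, 1.73 to 2.66). Over all barcodes the 3 measured markers of that set had a median ratio of 1.05 (0.890 to 1.38). The damage-associated microglia list had a median log2 ratio of 1.06 (0.97 to 1.27), higher in 36 of 38 measured members and above all 10000 random lists matched on expression. Among its members Apoe, a lipid carrier (ratio 2.08, 1.82 to 2.39), Trem2, a lipid-sensing receptor (2.06, 1.57 to 2.75), and its adaptor Tyrobp (2.20, 1.39 to 3.66) were higher. So were the engulfment receptor Axl (5.91, 2.79 to 14.98), the growth factor Csf1 (2.98, 1.44 to 7.15) and the chemokine Ccl3 (50 Cre and 1 control UMIs, ratio 15.1, 2.59 to 608). Atp6v0d2, a proton pump subunit, went the other way (0.151, 0.0516 to 0.39998). Cst7 (2.16, 0.974 to 5.64), Lpl (1.32, 0.716 to 2.64), Itgax (1.04, 0.523 to 2.26) and Spp1 (0.504, 0.166 to 1.69) had intervals that included 1, so no difference was detectable for them at this depth. Empty droplets of 100 to 200 UMIs also held more Tyrobp (113.5 against 53.6 CPM, with 176 and 80.0 CPM in the nuclei) and more Trem2 (131 against 71.8 CPM, with 471 and 229 CPM in the nuclei) in the Cre library. Apoe stood at 937 CPM in control nuclei, below the 2684 CPM of their empty droplets, and at 1948 CPM in Cre nuclei against 1471 CPM. The list median was 0.67 when each nucleus was weighted alike, 0.78 with microglia chosen by markers and 0.62 at the lowest in nuclei with few neuron marker UMIs. It was 1.27 after subtraction of that profile, 1.92 with separate clustering, 1.78 at a doublet rate of 0.06 and 1.67 with a minimum of 1000 UMIs.

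The share of nuclei with a UMI of a core set of damage-associated genes gave the same picture per nucleus. After thinning to 500 UMIs it was 39.9% in the Cre library (387 of 971, 36.8 to 43.0) and 16.8% in the control library (31 of 185, 11.7 to 22.9), a difference of 23.1 percentage points (16.3 to 28.7), with 3 Cre and 0 control nuclei left out. Unthinned, the shares were 52.5% and 27.6%. The background in excitatory neuron-like nuclei was 1.36% and 1.16% after thinning and 10.7% and 10.3% before. Other glia stood higher after thinning, at 13.02% and 9.25% in astrocyte-like nuclei (median depths 1254 and 1329) and 9.35% and 10.9% in oligodendrocyte-like nuclei (824 and 896) of the Cre and control libraries.

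The homeostatic microglia list did not stand apart. Its median was -0.00 (-0.11 to 0.16), at percentile 17.5 of the random lists, with 15 members higher and 15 lower. Tgfbr2, a receptor for TGF-beta (2.52, 2.02 to 3.18), was higher, whereas Lrba (0.555, 0.444 to 0.697) and Nav3 (0.749, 0.681 to 0.825, below 2 times its level in empty droplets) were lower. Csf1r (0.982, 0.842 to 1.15) and Tmem119 (0.871, 0.584 to 1.33) were not detectably different. The purinergic receptor P2ry12 had a ratio of 1.29 (1.06 to 1.60) but a log2 ratio of -0.085 when each nucleus was weighted alike. Cx3cr1 had a ratio of 0.811 (0.685 to 0.963) but log2 ratios of 0.52 with a minimum of 1000 UMIs and 0.38 at a doublet rate of 0.06, and the Cre mice carry a construct at or driven from that gene. The list median had no settled direction. It was 0.74 at a minimum of 1000 UMIs and 0.88 with separate clustering. At a doublet rate of 0.06 it was 0.61, and 0.57 with the mixed microglia and oligodendrocyte cluster added. However, it was -0.43 when each nucleus was weighted alike and -0.37 with microglia chosen by markers. In nuclei with few neuron marker UMIs it lay between -0.60 and -0.51.

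Interferon response genes were the most shifted list in microglia-like nuclei, with a median of 1.72 (1.40 to 2.14), higher in 20 of 21 members, above all random lists, and 1.66 with the 2 members at 0 control UMIs set to their bound. Bst2, an antiviral membrane protein, had 36 Cre and 0 control UMIs. Its ratio had a lower limit of 2.80 and was 3.63 against a floor of 3 counts. Bst2 stood at 41.4 CPM against 37.9 CPM in Cre empty droplets. Rnf213, an interferon-induced ubiquitin ligase, was higher (4.92, 2.61 to 10.5). The MHC and antigen presentation list (0.87, 0.57 to 1.33, 13 of 14 higher, percentile 100) was led by its transcriptional activator Nlrc5 (4.31, 2.11 to 10.2) and by H2-K1 (2.36, 1.59 to 3.64), which stood at 252 and 107 CPM against 137 and 158 CPM in empty droplets of the Cre and control libraries. The MHC median was 0 after ambient subtraction. Lysosome and phagocytosis genes (0.60, 0.53 to 0.77) were higher in 31 of 32 members at percentile 100, among them the protease Ctsd (2.05, 1.77 to 2.38). The phosphoinositide and immunoreceptor signalling list, to which Inpp5d itself belongs, had a median of 0.47 (0.29 to 0.64, 24 of 30 higher, percentile 99.9). The phospholipase Plcg2 (1.86, 1.40 to 2.52) and the adaptor Blnk (1.86, 1.44 to 2.44) were higher, and the kinase Syk was not detectably different (1.08, 0.736 to 1.64). Random lists were drawn from all genes of the class, and the summed microglia markers were themselves higher (1.45, 1.39 to 1.51). The percentiles therefore do not separate a change of state from a general rise of microglial RNA. The MHC, lysosome and signalling lists were not run in nuclei with few neuron marker UMIs.

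Metabolic and inflammatory lists were less uniform. Glycolysis and hypoxia genes had a median of 0.57 (0.30 to 0.99, 14 of 20 higher, percentile 99.96). Ldha (56 Cre and 1 control UMIs, ratio 16.9, 2.91 to 680) and Hif1a (3.35, 2.29 to 5.09) were higher. The glycolytic enzymes Pfkp (0.446, 0.248 to 0.817) and Hk1 (0.444, 0.231 to 0.877) were lower but below their level in empty droplets in both libraries, and Ldha was below 2 times that level. The lipid handling median was 0.36 (0.23 to 0.95, 18 of 22 higher, percentile 97.3). The fatty acid synthesis enzyme Acaca (3.32, 2.38 to 4.75) was higher, and Pparg (0.135, 0.0646 to 0.269) and Dgat2 (0.252, 0.0608 to 0.990) were lower. Dgat2 was below its level in empty droplets in both libraries, and Pparg, at 14.96 CPM against 84.7 CPM, in the Cre library. Inflammatory cytokine and NF-kB genes (0.33, 10 of 15 higher, percentile 92.5) lay within the range of random lists. However, Tlr2 had 17 Cre and 0 control UMIs (lower limit 1.25, 1.71 against the floor) and Nfkb1 was higher (1.502, 1.15 to 1.98). The antioxidant list was also within that range (0.08, 8 of 14 higher, percentile 74.2), with Nfe2l2 higher (2.49, 1.64 to 3.94) and Sod2 lower (0.369, 0.189 to 0.731) but below its level in empty droplets. Alzheimer risk genes as a group (0.22, 22 of 32 higher, percentile 77.8) did not stand apart, with Apbb2 higher (2.31, 1.89 to 2.85) and App lower (0.728, 0.588 to 0.907) but below its level in empty droplets. Proliferation genes were lower in 9 of 11 measured members (-0.81, -1.22 to -0.09, percentile 0.405), including Kif11, a mitotic motor (0.216, 0.0540 to 0.790), at 5 Cre and 7 control UMIs.

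Ranked over all genes without regard to lists, the highest in the Cre microglia-like nuclei was Lrguk, at 68 Cre and 0 control UMIs (lower limit 5.42, 6.85 against the floor). It was followed by the inhibitory receptor Cd300lf (95 Cre and 1 control UMIs, ratio 28.7, 5.03 to 1146), the cell cycle complex subunit Anapc15 (5.71, 3.90 to 8.67), Lrmda (3.20, 2.89 to 3.54) and the long non-coding RNA Pvt1 (3.67, 2.81 to 4.89). Next came Prr5l (16.3, 2.81 to 656), the ATP-gated channel P2rx4 (5.01, 2.81 to 9.86), Axl, the Ras exchange factor Rasgrp3 (3.49, 2.72 to 4.55) and the potassium channel Kcnj2 (8.16, 2.69 to 40.4). The 10 lowest, all of them also detected in excitatory and inhibitory neuron-like nuclei, were Meis2 (0.0342, 0.0218 to 0.0514), Dpp6 (0.125), Kcnb2 (0.155), Auts2 (0.172), Cpne4 (0.138), the migration gene Dcx (0.151), the presynaptic Nrxn3 (0.231), Dync1i1 (0.197), Eml5 (0.197) and Epha5 (0.226). Of these, Kcnb2, Cpne4, Dcx, Nrxn3, Dync1i1, Eml5 and Epha5 were below 2 times their level in empty droplets, as was Prr5l. Meis2 was also a leading gene of the unnamed cluster that held 552 control and 22 Cre nuclei. Lrguk lies on chromosome 6 from 34029448 to 34134034, Axl on chromosome 7 from 25757273 to 25788705 and Apoe on chromosome 7 from 19696109 to 19699188. Prr5l, which is also a marker of oligodendrocytes, had no settled direction, since its log2 ratio was -0.42 without doublet removal.

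Summed over nuclei, transcripts of other cell types also differed between the microglia-like nuclei of the 2 libraries. The synaptic list was lower in all 30 members (median -1.06, -1.18 to -0.91, percentile 0) and the homeostatic astrocyte list in 18 of 19 (-0.64, -1.22 to -0.58, percentile 0.05), whereas the summed 20 microglia markers were higher (1.45, 1.39 to 1.51). Per nucleus, excitatory and inhibitory neuron markers had a median of 13.8 UMIs per 10000 in both libraries. Their 90th percentile was 62.98 in the control and 38.1 in the Cre library. With the synaptic list added the medians were 69.3 and 78.3, the 90th percentiles 353 and 143. With all neuron markers they were 30.02 and 25.35, and 78.1 and 57.6. The medians thus had no common direction, but the upper tail was higher in the control library each time. In the nuclei with few neuron marker UMIs, taken with 3 choices of markers, the synaptic median lay between -0.05 and 0.09 and the damage-associated median between 0.62 and 1.11. The choice that gave 0.09 included the synaptic list itself, so that value follows from the selection. The other choices selected for few neuron markers, so their synaptic medians check the selection only. The interferon median lay between 1.01 and 1.35, the homeostatic median between -0.60 and -0.51, and the Inpp5d log2 ratio between -2.18 and -2.11. Over all genes of the class the median log2 ratio was 0.12, and TMM scaling raised it to 0.27, so list medians above are to be read against a centre that itself moved by 0.15.

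**Figure D2:**
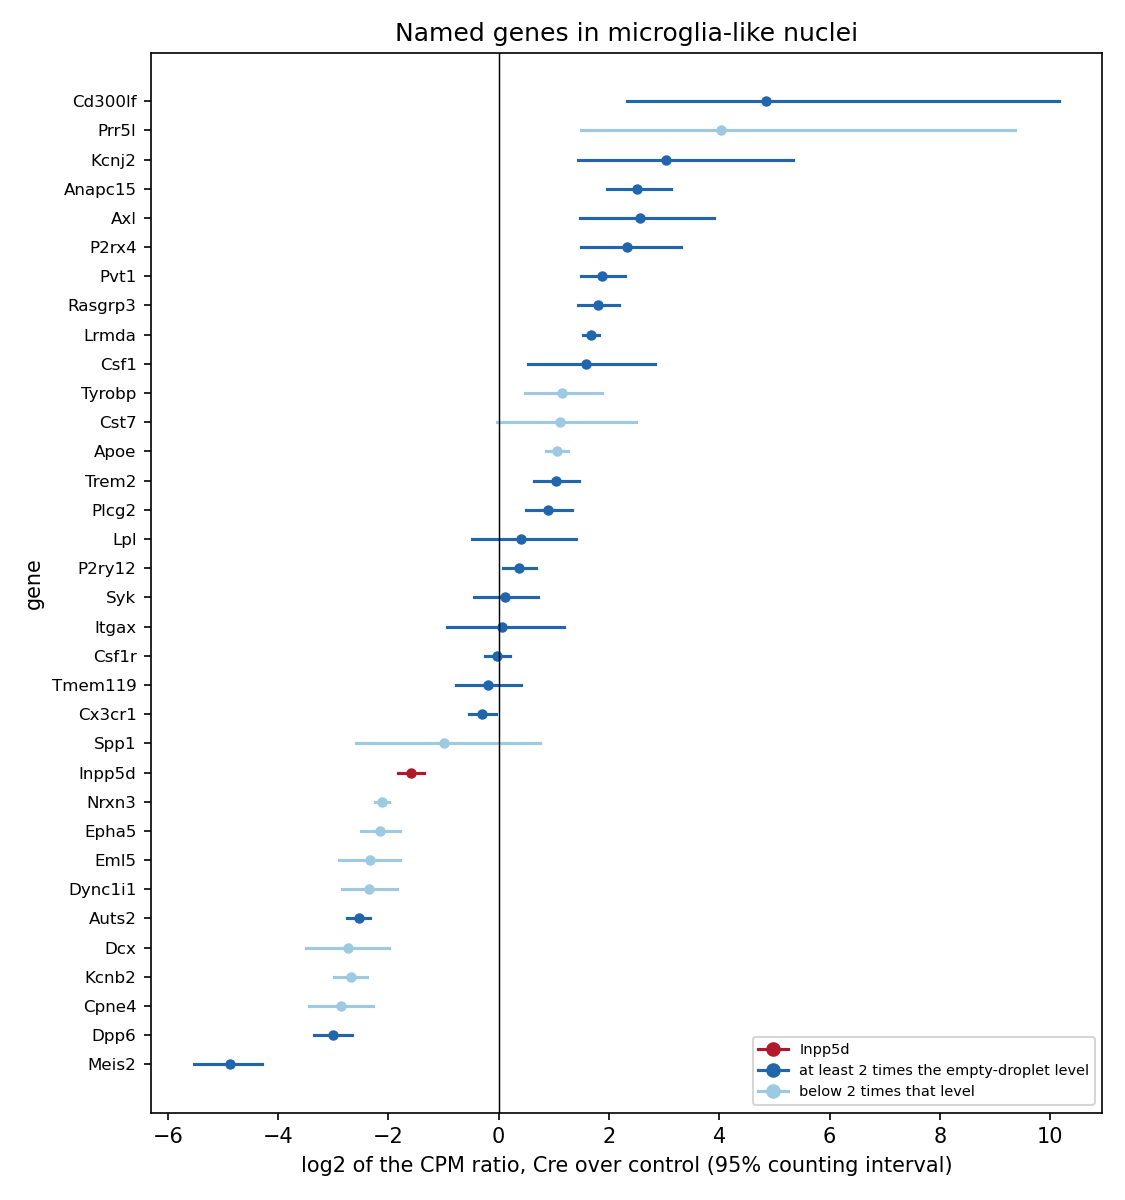
The horizontal axis is the log2 ratio of CPM in microglia-like nuclei, Cre over control library, for the genes on the vertical axis, with lines for the 95% counting interval and Lrguk left out because its control count was 0. Inpp5d (red) lies below 0, Cd300lf, Anapc15 and Axl lie above 0, and the genes in pale blue were below 2 times their level in empty droplets of 100 to 200 UMIs.

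The remaining lists run in microglia-like nuclei belong to other cells. The reactive astrocyte list had a median of 0.42 (0.10 to 0.76, 12 of 19 higher, percentile 95.2, and 0.39 with its member at 0 set to the bound). Its members Apoe and Cd9 (2.32, 1.71 to 3.20) were higher. The disease-associated oligodendrocyte list had a median of 0.74 (0.50 to 1.17, 13 of 18 higher, percentile 99.97, 0.66 with the bound). Its member Nlrc5 was higher. The myelin list (0.08, 7 of 14 higher, percentile 45.1), immediate early genes (-0.35, 3 of 9 higher, percentile 14.0) and the stress and unfolded protein list (0.00, 4 of 8 higher, percentile 50.04) lay within the range of random lists.

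Astrocyte-like nuclei formed the fourth comparison. Reactive astrocyte genes were higher in the Cre library, with a median of 0.63 (0.17 to 0.72), 21 of 30 members higher and no random list as high. The median was 0.11 when only members with 50 UMIs or more were kept, and 0 after subtraction of the ambient profile, which left 10 of the 30 members at 0 in both libraries. With the empty droplet profile subtracted instead, the median stayed within its counting interval. Gfap, the intermediate filament of reactive astrocytes, was higher (2.24, 1.88 to 2.67), as were Vim (3.24, 1.31 to 9.13), the protease inhibitor Serpina3n (31 Cre and 3 control UMIs, 12.4, 3.85 to 63.1) and the complement component C4b (2.88, 2.31 to 3.60). Id3 (0.552, 0.425 to 0.712) was lower. All 16 measured interferon response genes were higher (median 1.72, 1.25 to 2.40, percentile 100). Among them were Oasl2 (31 Cre and 3 control UMIs, 12.4, 3.85 to 63.1) and Cxcl10 (15 Cre and 0 control UMIs, lower limit 4.29, 5.98 against the floor). MHC genes were higher in 6 of 7 (0.65, 0.08 to 1.20, percentile 99.6), led by Nlrc5 (24 Cre and 3 control UMIs, 9.56, 2.90 to 49.6).

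The homeostatic astrocyte list stayed at -0.00 (-0.04 to 0.05, 12 of 25 higher, percentile 10.1), with the water channel Aqp4 (1.04, 0.915 to 1.18) and the glutamate transporter Slc1a2 (1.02, 0.996 to 1.05) not detectably different. The lipid handling list (0.13, -0.20 to 0.22, 12 of 23 higher, percentile 90.6) held Pparg, which was higher (4.44, 1.88 to 12.1), and Apoe (0.690, 0.660 to 0.721) and Scd2 (0.611, 0.529 to 0.704), which were lower. Over all genes the highest were the asparaginase gene Aspg (13.9, 6.09 to 39.3), Ankrd55 (15.8, 5.83 to 60.3), the antiviral helicase gene Ddx60 (6.07, 3.32 to 11.99), Plce1 (2.83, 2.36 to 3.41) and Rbms3 (2.68, 2.35 to 3.07). The lowest were the Notch target Hes5 (0.352, 0.274 to 0.448), the adhesion molecule Vcam1 (0.361, 0.235 to 0.540), Tmtc4 (0.308, 0.166 to 0.541), Wdr17 (0.522, 0.495 to 0.550) and Pigk (0.480, 0.405 to 0.566). After ambient subtraction the interferon median was 0.68 and the MHC median 0. Tmtc4, Vim, Apoe, Scd2 and Pparg were below 2 times their level in empty droplets.

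In oligodendrocyte-like nuclei, disease-associated oligodendrocyte genes were higher, with a median of 0.53 (0.17 to 0.81), 12 of 18 members higher and no random list as high. C4b had the largest shift (9.72, 5.86 to 17.2, from 140 Cre and 17 control UMIs), and B2m (4.20, 1.958 to 10.0) and H2-K1 (3.67, 1.69 to 8.85) of the class I antigen presentation machinery were higher but far below their level in empty droplets: B2m stood at 45.0 and 10.7 CPM against 183 and 169 CPM, and H2-K1 at 39.4 and 10.7 CPM against 137 and 158 CPM. Serpina3n, at 4 Cre and 2 control UMIs (2.36, 0.338 to 26.1), and Il33 (1.04, 0.887 to 1.23) were not detectably different. All 4 measured MHC genes were higher (1.35, 0.85 to 2.10, percentile 100), and 4 of 6 interferon genes (0.55, -0.13 to 1.04, percentile 99.7), including Xaf1 (2.07, 1.22 to 3.57).

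The myelin list stayed at 0.00 (-0.07 to 0.09, 10 of 20 higher, percentile 4.81). Mobp was higher (1.37, 1.28 to 1.48), Cnp (0.597, 0.457 to 0.776) lower, and Mbp not detectably different (1.05, 0.999 to 1.11). Other high genes were the growth factor gene Pdgfc (3.20, 1.91 to 5.57), Rcan2 (2.17, 1.86 to 2.52), Zbtb16 (2.01, 1.68 to 2.41) and Fam169a (2.60, 1.59 to 4.35). The lowest were Dpp6 (0.138, 0.101 to 0.184), Ptpro (0.114, 0.0575 to 0.207), Pbx3 (0.345, 0.269 to 0.438), Dync1i1 (0.456, 0.352 to 0.585) and Scd2 (0.594, 0.532 to 0.662), of which Ptpro and Pbx3 also led the unnamed cluster that held 552 control and 22 Cre nuclei. Pdgfc, Fam169a, Dpp6, Ptpro, Dync1i1 and Scd2 were below 2 times their level in empty droplets. Ambient subtraction set the MHC and disease-associated medians to 0, the latter with 6 of its 18 members at 0 in both libraries. With the empty droplet profile subtracted instead, the disease-associated median stayed within its counting interval. Without doublet removal the log2 ratios of Dpp6 and Pbx3 shrank from -2.85 to -0.42 and from -1.53 to -0.29.

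In neurons the activity-related genes were lower in the Cre library while synaptic genes were close to equal. All 20 immediate early genes were lower in excitatory neuron-like nuclei (median -0.84, -0.86 to -0.57, below every random list), including Fos (0.482, 0.350 to 0.656), Arc (0.697, 0.619 to 0.784), Egr1 (0.761, 0.688 to 0.841), Fosb (0.309, 0.192 to 0.482) and Egr4 (0.377, 0.271 to 0.517). All 17 measured stress and unfolded protein response genes were lower too (-0.49, -0.73 to -0.39, percentile 0.660), among them the endoplasmic reticulum chaperone Hspa5 (0.495, 0.441 to 0.554) and Gadd45b (0.443, 0.328 to 0.594). The synaptic list had a median of 0.04 (0.02 to 0.06, 19 of 30 higher, percentile 39.9). Syt1 (1.18, 1.17 to 1.19) and Nrxn3 (1.13, 1.12 to 1.14) were slightly higher and Vamp2 (0.767, 0.707 to 0.831) and Nlgn2 (0.758, 0.682 to 0.841) lower. The amyloid precursor gene App (0.977, 0.953 to 1.00) was not detectably different and changed sign with TMM scaling, and Thy1, the gene whose promoter drives the 5xFAD transgenes, had a ratio of 0.903 (0.872 to 0.936). Thy1 stood at 277 and 306 CPM against 1103 and 1516 CPM in empty droplets of the Cre and control libraries.

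Inhibitory neuron-like nuclei went the same way: 16 of 17 immediate early genes were lower (-1.06, -1.38 to -0.60, percentile 0), including Egr1 (0.391, 0.213 to 0.690). There, 12 of 13 stress genes were lower (-0.54, -0.77 to -0.23, percentile 1.16), among them Hspa5 (0.424, 0.325 to 0.547) and Hsp90b1 (0.673, 0.563 to 0.804). The synaptic median was 0.05 (0.01 to 0.11, 19 of 30 higher, percentile 45.2). There Grin2a (1.27, 1.22 to 1.33) and Nrxn3 (1.14, 1.12 to 1.16) were higher and Vamp2 (0.631, 0.509 to 0.780) was lower. By rank over all genes, Acpp (57 Cre and 3 control UMIs, 20.6, 6.69 to 103), Pld5 (2.10, 1.95 to 2.27) and Tekt1 (2.84, 1.80 to 4.61) were highest in excitatory neuron-like nuclei and Col6a4 (0.135, 0.0594 to 0.271), Fermt1 (0.178, 0.0981 to 0.305) and Hspb3 (0.159, 0.0730 to 0.311) lowest. Of these, Acpp, Pld5, Tekt1 and Hspb3 were below 2 times their level in empty droplets. In inhibitory neuron-like nuclei these were Slc22a4 (2.58, 1.49 to 4.63), Ndst4 (1.86, 1.46 to 2.37) and Col24a1 (2.23, 1.45 to 3.50) against Btk (0.230, 0.112 to 0.438), Slc6a20b (0.280, 0.156 to 0.478) and Tceal6 (0.260, 0.129 to 0.486). In empty droplets of 100 to 200 UMIs the same genes were also lower in the Cre library and mostly above their level in neurons: Hspa5 stood at 154 against 307 CPM, Egr1 at 69.0 against 136, Fos at 12.7 against 26.6, Arc at 15.8 against 39.2 and Gadd45b at 5.15 against 18.5. With the profile of those droplets subtracted, the immediate early gene medians were -0.80 in excitatory and -0.96 in inhibitory neuron-like nuclei and the stress medians -0.33 and -0.35. Slc22a4, Ndst4, Tceal6 and the synaptic genes named for both classes were below 2 times their level in those droplets, except Nrxn3 in inhibitory neuron-like nuclei. Neuronal clusters differed in share between the libraries, so genes of single neuron types can move with those shares. Pooling ratios within clusters left the immediate early gene median within its counting interval.

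The smaller classes were read by rank over all genes. In oligodendrocyte precursor-like nuclei Frmd4a (2.25, 2.01 to 2.52), the adhesion molecule Nfasc (1.87, 1.60 to 2.19) and Pdcd4 (2.24, 1.53 to 3.36) were highest, and Tsix (0.478, 0.359 to 0.633), Lgr5 (0.382, 0.216 to 0.659) and Gpr17, a receptor of differentiating precursors (0.557, 0.416 to 0.744), lowest. Lgr5 also led the unnamed cluster with 552 control nuclei. In endothelial-like nuclei Mapk4 (2.58, 1.31 to 5.53), B3galt1 (1.76, 1.27 to 2.46) and Clint1 (1.97, 1.24 to 3.22) were highest and Id1 (0.269, 0.163 to 0.432), Fli1 (0.398, 0.304 to 0.518) and Cobll1 (0.474, 0.340 to 0.659) lowest. In fibroblast-like nuclei these were Foxp2 (1.63, 1.32 to 2.01), Naaladl2 (1.87, 1.30 to 2.69) and Vcl (1.87, 1.23 to 2.85) against Prg4 (0.420, 0.260 to 0.653), Rassf8 (0.310, 0.119 to 0.686) and Igfbp5 (0.301, 0.105 to 0.708). In pericyte or smooth muscle-like nuclei Mir99ahg (2.14, 1.36 to 3.42), Ptprk (1.83, 1.33 to 2.52) and Sept11 (2.01, 1.30 to 3.13) were higher and Malat1 (0.824, 0.779 to 0.871) and Pde8b (0.792, 0.645 to 0.969) lower. In striatal projection neuron-like nuclei the guidance genes Slit2 (16.8, 10.4 to 28.9) and Unc5d (7.20, 5.79 to 9.03) and the cadherin Cdh13 (6.17, 4.98 to 7.69) were highest and Rbm4b (0.265, 0.145 to 0.458), P2ry14 (0.318, 0.208 to 0.474) and Far1os (0.277, 0.147 to 0.489) lowest. Pdcd4, Mapk4, B3galt1, Slit2 and Unc5d were below 2 times their level in empty droplets. With TMM scaling all log2 ratios were higher by 0.15 in endothelial-like and lower by 0.11 in fibroblast-like nuclei.

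**Figure D3:**
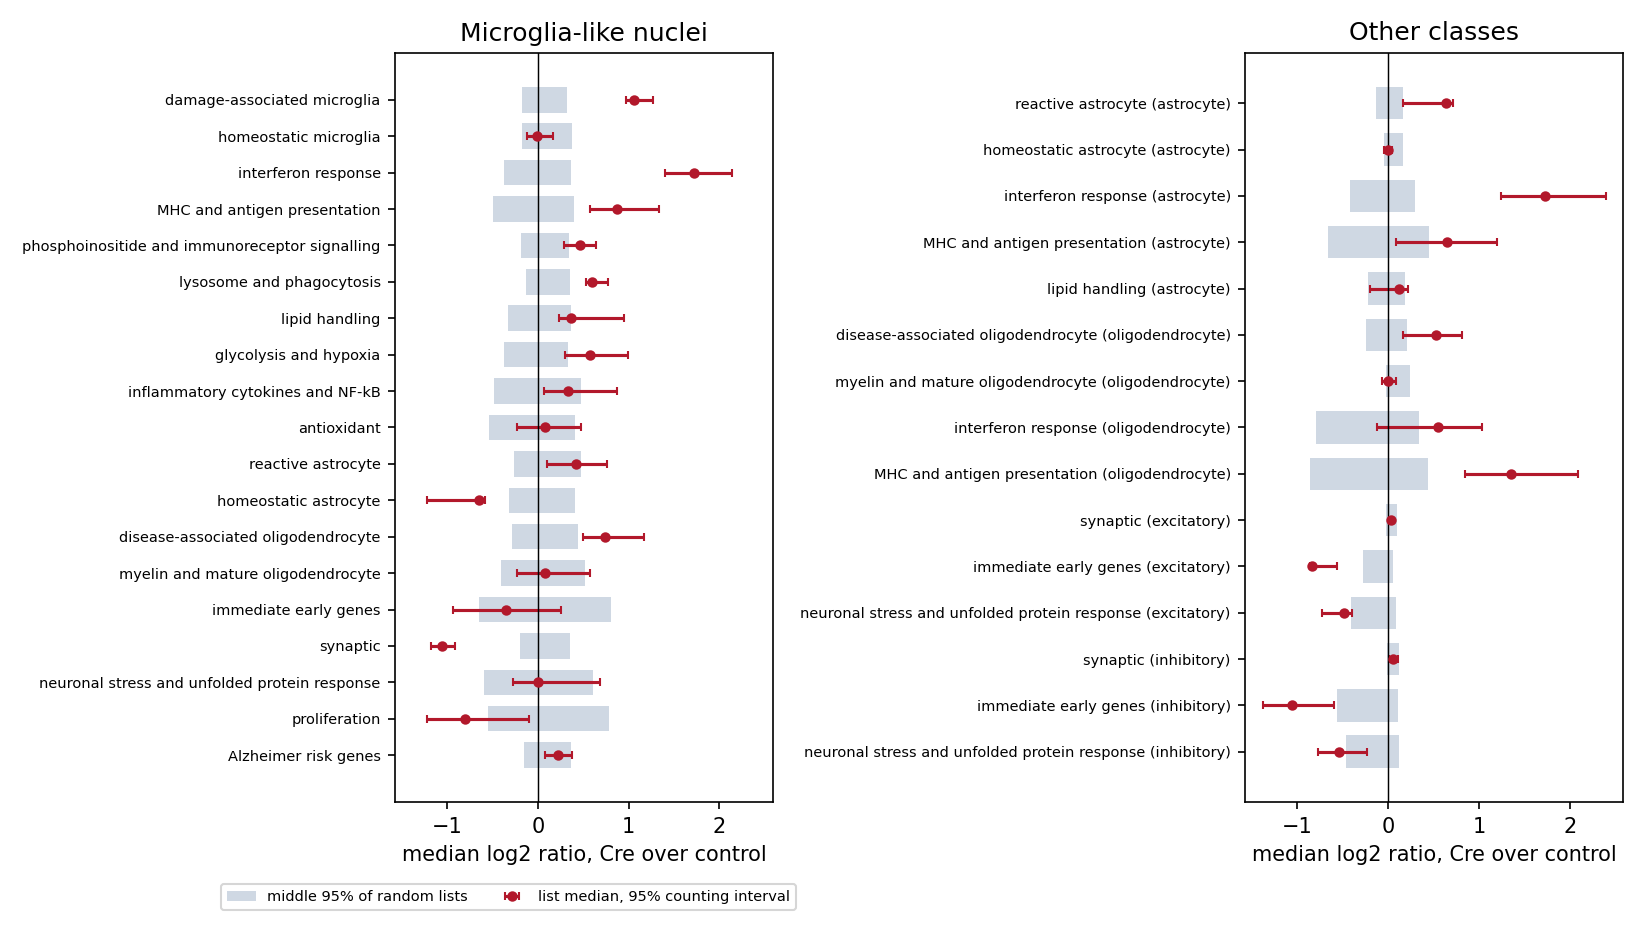
The horizontal axes give the median log2 ratio, Cre over control library, of each fixed list on the vertical axis, with red points and lines for the median and its 95% counting interval and grey bars for the middle 95% of 10000 random lists matched on expression. Damage-associated (1.06) and interferon (1.72) lists in microglia-like nuclei lie above their grey bars, and immediate early genes lie below theirs in excitatory (-0.84) and inhibitory (-1.06) neuron-like nuclei.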

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

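Chosen only after the result was seen were the tests of doublet removal and mixed clusters, of fewer neuronal nuclei and of free RNA in barcodes of nuclei, the barcode overlap at like UMI totals and its use against the bound on plain chance, the reading of the control genes used there and the readings of marker sets, and values related to the other tests had also been seen.

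The microglia-like share was 5.36 times as high in the Cre library. Calling and the UMI minimum as the whole cause are argued against only in part by the microglia markers over all barcodes, with a median ratio of 2.31 (2.22 to 2.43). This is less than the ratio of nuclei and leaves part of the difference open to them. The measure also mixes the number of microglia with their marker level. Within microglia-like nuclei the summed markers were themselves higher (1.45, 1.39 to 1.51). How much of the share ratio came from calling therefore cannot be told. Doublet removal and mixed clusters left a log2 share ratio of at least 1.72 over the alternatives run (1.72 to 2.51), and a loss of neuronal nuclei would have raised the other glia alike, but the higher of the astrocyte and oligodendrocyte ratios was 1.04 (0.941 to 1.15), although that of oligodendrocyte precursors was 1.41 (1.19 to 1.68). A difference in dissection, pooling or library preparation stays open, since each group had 1 library, and so does the genotype, which was not tested apart from the library.

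Damage-associated and interferon genes in microglia-like nuclei and interferon genes in astrocyte-like nuclei were higher in the Cre library. Neuronal RNA mixed into control microglia-like nuclei as the whole cause is argued against by nuclei with few neuron marker UMIs, where the lowest damage-associated median was 0.62 (0.48 to 0.93), smaller than the 1.06 of all such nuclei. Microglial RNA in astrocyte-like nuclei was estimated at 2.71% in the control and 2.61% in the Cre library, and the astrocyte interferon median after its subtraction was 1.71 (1.20 to 2.45). Monocytes or neutrophils among the microglia-like nuclei stay open, since their summed markers were also higher (ratio 2.14, 1.73 to 2.66), as do differences between mice, pools and library preparations beside the genotype. Over all barcodes the 3 measured markers of that set had a median ratio of only 1.05 (0.890 to 1.38). Which single markers carried the sum was not tested.

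Transcripts typical of lung, a list of 12 genes, were present in both libraries, at 46263 CPM in control and 21812 CPM in Cre barcodes of over 200 and under 500 UMIs but 35.0 and 20.2 CPM in barcodes of at least 500. Barcodes rich in them were shared between the libraries 27.8 times (27.3 to 28.4) as often as plain chance at the lowest of 6 readings and 69.1 times at the highest, which may reflect molecules of another library carried over with their barcodes. Barcodes that hold more molecules of any kind stay open as well and cannot be told apart from this: excitatory neuron markers were shared 0.351 times (0.192 to 0.589) as often as plain chance, but among barcodes of like UMI totals 2.05 times (1.12 to 3.45), as much as the 1.80 to 2.40 times of lung-type genes, and carried-over molecules would themselves raise those totals. Free RNA in the suspension was left undecided by the test written first (0.532, 0.390 in the other library), while barcodes of at least 500 UMIs held 0.166 (0.157 to 0.174) of the lung-type UMIs of as many empty droplets in the control and 0.113 (0.105 to 0.121) in the Cre library. No biological explanation was tested.

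Clusters outside the named classes also differed in share between the libraries, without a test between groups. An unnamed cluster led by C130073E24Rik, Pbx3 and Meis1 had a ratio of 4.45 (51 control and 223 Cre nuclei). The cluster with microglia and oligodendrocyte markers had a ratio of 1.41 (104 and 144 nuclei). A cluster led by Dnah12 and Cfap299 had a ratio of 2.78 (11 and 30 nuclei). Only unnamed clusters higher in the Cre library were flagged by the rule used here. Others were lower, at ratios of 0.0406 (0.0252 to 0.0621, 552 control and 22 Cre nuclei), 0.477 (0.409 to 0.555, 538 and 252) and 0.686 (0.562 to 0.836, 254 and 171).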

How the results depend on the processing

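The doublet rates of 0.06 and 0.05, both uses of the empty droplet profile, the choice of microglia-like nuclei by markers, the added mixed cluster and the share among glial nuclei were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Of the values that answer a comparison, 78 under alternatives set in advance stayed within their counting interval and 20 moved beyond it, and under added alternatives 74 and 15. Of other values 459 stayed, 108 moved and 3 reversed, and under added alternatives 822, 65 and 2. The rank-based UMI threshold called 12166 nuclei and gave no microglia cluster, so no microglia value. With a minimum of 1000 UMIs, fewer nuclei by construction, Inpp5d was -0.63, the log2 share ratio 1.07, the core difference 29.4 points, the damage-associated median 1.67, the homeostatic median 0.74 and Cx3cr1 reversed to 0.52. With separate clustering Inpp5d was -0.57, the share 1.72, the damage-associated median 1.92 and the homeostatic median 0.88. Without doublet removal the share was 2.18 and Prr5l reversed to -0.42. At a doublet rate of 0.06 Inpp5d was -0.96, the share 2.13, the damage-associated median 1.78, the homeostatic median 0.61, Prr5l reversed to -0.066 and Cx3cr1 to 0.38. With the mixed cluster added these were -0.83, 1.98, 1.68 and 0.57. With microglia chosen by markers Inpp5d was -2.01, the damage-associated median 0.78 and the homeostatic median -0.37. The share among glial nuclei was 1.89. With nuclei weighted alike Inpp5d was -2.06, the damage-associated median 0.67, the homeostatic median -0.43, immediate early genes -0.93 and P2ry12 reversed to -0.085. Immediate early genes were -0.87 at a doublet rate of 0.05 and -0.88 with the ambient test against empty droplets. TMM scaling gave a synaptic median of 0.10. Ambient subtraction set the reactive astrocyte and disease-associated oligodendrocyte medians to 0, through members at 0 in both libraries, and with the empty droplet profile the damage-associated median was 1.27. A minimum of 50 UMIs gave a reactive astrocyte median of 0.11, and thinning to 1000 UMIs a core difference of 31.0 points. Where no construction is named, the cause was not tested. Inpp5d stayed negative (-2.06 to -0.57) and the damage-associated median positive (0.67 to 1.92) over the alternatives of this part that gave a value, and in nuclei with few neuron marker UMIs they reached -2.18 and 0.62.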

Other observations

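The marker sums, the barcodes below the UMI minimum and the shared barcodes were chosen after results had been seen.

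Within microglia-like nuclei the summed markers of monocytes or neutrophils were higher in the Cre library (708 Cre and 100 control UMIs, ratio 2.14, 1.73 to 2.66), whereas those of perivascular macrophages were lower (0.511, 0.373 to 0.706). Over all barcodes the median ratios of these 2 sets were 1.05 (0.890 to 1.38, 3 markers) and 0.967 (0.858 to 1.02, 8 markers). Lymphocyte markers had a ratio of 1.33 (0.811 to 2.28). Markers of inhibitory neurons (0.249, 0.220 to 0.281), endothelial cells (0.426, 0.352 to 0.515), excitatory neurons (0.647, 0.579 to 0.724), oligodendrocyte precursors (0.630, 0.504 to 0.790), striatal projection neurons (0.798, 0.688 to 0.928) and astrocytes (0.818, 0.703 to 0.955) were lower. Markers of oligodendrocytes (1.20), neurons of other regions (1.08), pericytes (0.790), fibroblasts (0.488) and ependymal cells (0.786) had intervals that included 1.

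Genes that led the unnamed cluster with 552 control and 22 Cre nuclei recurred among the lowest genes of other classes: Meis2 in microglia-like, Ptpro and Pbx3 in oligodendrocyte-like and Lgr5 in oligodendrocyte precursor-like nuclei. Barcodes of microglia type, with at least 60 microglia marker UMIs per 10000, were also more numerous below the UMI minimum in the Cre library. They numbered 210 of 3045 Cre against 31 of 1706 control barcodes at 200 to under 300 UMIs. At 300 to under 500 UMIs they numbered 168 of 868 against 43 of 619. At these depths very few marker UMIs meet the rule, and the part due to empty droplet RNA was not tested. Of the nuclei barcodes, 24 occurred in both libraries against 35.3 by chance (0.680, 0.436 to 1.01). Other unnamed clusters held 538 control and 252 Cre, 254 and 171, 141 and 147, and 31 and 17 nuclei.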
